A study of Mus musculus with 8 samples.

How the data were processed

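RNA from the stomach corpus of 4 control and 4 mutant mice was collected in RNAlater, extracted with Trizol and made into polyA libraries with a NEBNext Ultra RNA kit, per the labels' protocols. The authors deposited raw read counts per Ensembl gene and FPKM values for the same genes. CASAVA, fastp, STAR 2.5 and featureCounts are named in the submitters' processing notes, without roles. The genome build and the strand setting of the counting are not given in the sources used here, so genes that overlap or lie antisense to one another, and members of near-identical families, are uncertain. Of 54495 table genes shared with GENCODE M21 (GRCm38), out of 54532, 53585 had the same start and end, and coordinates are given as in the count table. A library size was read from the deposited FPKM as the median, over well-counted genes, of the count divided by FPKM and gene length. It lay between 0.994 and 1.02 times the TMM library size. Departures of single genes from it were not checked. The FPKM fits thus carry nearly the same scaling and are no separate check of it.

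Columns were matched to samples by name. One control column, headed SCI, was read as SC1, with a capital I for the 1. Each library is 1 animal per the series' design text. Within groups no pair of libraries agreed within sampling noise (smallest chi-square per degree of freedom 14.2), so each counted as 1 replicate. Library totals lay between 18184281 and 23814720 reads. A floor of 3 counts per library was on average 0.189 CPM in controls and 0.120 CPM in mutants, and floors and count intervals (95%, exact binomial) cover counting error only.

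Genes were kept by edgeR's filterByExpr, scaled with TMM factors and tested with edgeR's robust quasi-likelihood test (edgeR 4.0.16, R 4.3.3), mutant over control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene is from this test unless another tool is named. The SE of a log2 fold change was taken as the size of the fitted coefficient without prior count, in log2 units, divided by the square root of the test's F value, and was left out where a group had no reads. CPM are counts over TMM library sizes, given as mean ± SD with n = 4. Of 43 gene lists, 42 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, with fry, and by exact permutation of the libraries' mean log2 CPM (two-sided, 70 assignments). The remaining list, of sex-linked genes, was a check. The p of a list is from camera with the preset correlation unless stated, adjusted over the 42 lists. Camera compares a list with all other genes, whereas fry asks whether its genes move one way.

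The test, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. Apart from Prkaca, Six2 and the sex-linked check, that rule took genes by their p or fold change in these data. Named were Prkaca and Six2. Of called genes with a mean CPM of at least 1 whose groups did not overlap, the 10 largest rises and the 10 largest falls were named, leaving out predicted genes, pseudogenes and receptor segments. In each list past camera the 3 members with the smallest p were named, and in other lists 1. Where a list had calls in both directions, the largest change in the rarer direction was added. Together with the sex-linked genes this gave 107 genes, of which a part is printed, after leaving out 2 that are not reported here. These 2 stayed in the gene and list tests.

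The alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE size factors, scaling on genes outside the parietal and chief cell lists, no low-count filter or a stricter one (CPM of at least 1 in 4 libraries), the replicate number as a block, each library left out in turn, the smooth muscle score or the Y-linked score as a covariate, stricter thresholds, protein-coding genes alone, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) with a mean FPKM of at least 0.5 or no filter. Column totals as library sizes, and leaving out both libraries with squamous transcripts, were added after seeing the data. A change of sign counted as a reversal where the result was called in either of the fits compared. Pairing by replicate number was checked by the correlation of same-numbered libraries' deviations from their group means.

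The gene tests and camera were run on simulated counts for the 15862 genes of this comparison, with 200 genes changed and a further list of genes raised. Counts were drawn independently per gene, so camera's preset correlation was not checked. Far fewer genes changed there than the 3208 called in the data, so the shares recovered may differ in the data. edgeR recovered 18% of the genes changed 2-fold and 58% of those changed 4-fold, with 7.22% of its 97 calls false. DESeq2 recovered 43% and 81%, with 29.1% of 199 calls false, and voom 16% and 53%, with 4.65% of 86 calls false.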

Results

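RNA was sequenced from the corpus of the stomach, the acid- and pepsinogen-secreting region, of 8 mice on a mixed C57BL/6 and CD1 background. All 8 carried the Six2-Cre transgene. The 4 controls had 2 unmodified copies of the gene for the alpha catalytic subunit of protein kinase A (PKA), and the 4 mutants carried 1 floxed PKAcaR copy, an allele known from the literature to encode a form of the enzyme that is active without cyclic AMP once Cre has recombined it. No treatment was given, and per the series' design text each library came from a separate animal. The total count per library lay between 18942308 and 22814152 reads in controls and between 18184281 and 23814720 in mutants, over 54532 annotated genes. Transcripts of Pgc, the pepsinogen C gene, took 20.7% to 31.2% of all counted reads in controls and 0.107% to 4.60% in mutants. The 10 most abundant genes took 38.8% to 50.8% in controls and 8.69% to 15% in mutants. The single comparison asked which genes differed between mutant and control corpus.

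Prkaca, the gene the allele alters (ENSMUSG00000005469, chromosome 8, 83972993 to 83996443 in GRCm38), was measured at 80.2 ± 4.05 CPM (read counts scaled to library size with TMM factors) in controls and 37.9 ± 1.87 in mutants (SD, n = 4 each). Its log2 fold change, mutant over control, was -1.08 with a standard error (SE) of 0.085 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000604), and all 4 mutants lay below all 4 controls. Relative to the control mean the 4 mutants held 0.459, 0.508, 0.462 and 0.463. The counts cannot separate transcripts of the modified and the unmodified copy. With column totals as library sizes, a scaling that raised the median log2 fold change of all genes by 0.70, the log2 fold change of Prkaca was -0.38 (SE 0.12, adjusted p = 0.0208), and all 4 mutants again lay below all 4 controls, mutant 2 (0.8462 of the control mean) by less than counting error from control 3 (0.8479). Prkaca and Pkia, a PKA inhibitor gene, fell among the 12 tested members of the PKA subunit and inhibitor list, which did not pass camera (adjusted p = 0.0730) and passed fry (adjusted p = 0.0290). Pkia was named after its values were seen, and without any 1 control, mutant 1 or mutant 4 the list had 1 member lower. Without mutant 2, 6 members fell and the list passed (adjusted p = 0.0044, and 0.162 with an estimated correlation). With column totals 4 members were higher and 1 lower, with a mean log2 fold change of 0.33 (adjusted p = 0.114). Six2, whose promoter drives the Cre (ENSMUSG00000024134, chromosome 17, 85684277 to 85688274), was at 11.4 ± 4.81 CPM in controls and 8.28 ± 12.7 in mutants, which did not pass (log2 fold change -0.46, SE 0.99, adjusted p = 0.769). Mutant 2 alone held 667 Six2 reads, against 33 to 77 in the other mutants, and without it Six2 was lower (log2 fold change -2.55, SE 0.50, adjusted p = 0.00483).

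By camera with a preset correlation, the lists of parietal, chief and endocrine cells, of smooth muscle and enteric neurons and of mitochondrial energy genes were lower in the mutant corpus, and those of mucous neck cells, metaplasia, antimicrobial genes and cytokines were higher. Of 15862 genes tested, 3208 differed (edgeR, adjusted p under 0.05), 1489 higher and 1719 lower in mutants. At least 2-fold changes made up 1910 of these, 863 higher and 1047 lower. In 3133 of the 3208 genes all 4 mutants lay on one side of all 4 controls. Over all genes tested 4800 had groups that did not overlap, where chance would give 2.86%. Of the 42 gene lists tested, 12 were higher and 12 lower by camera with a preset correlation, and 26 differed in an exact permutation test of the libraries' list scores (two-sided, p = 0.0286, the smallest that 70 assignments allow, adjusted p = 0.0462). Among the 26 were the pit, intestinal, isthmus, mesothelium and EGF receptor ligand lists, which did not pass camera. The macrophage, interferon and proliferation lists passed camera but not the permutation test. No list passed camera with an estimated correlation (smallest adjusted p = 0.164, with 8 lists at an unadjusted p under 0.05), while 21 passed fry. 1 mutant library, mutant 2, stood apart from the rest. Its log2 CPM values correlated across genes with those of the other mutants at 0.83 to 0.875, against at least 0.972 among the other 3 mutants, and without it 5400 genes differed (2447 higher and 2953 lower). Leaving out control 1, 2 or 3 gave 1717, 1941 and 1723 genes, and leaving out mutant 4 gave 1926. Below, values without one library come from the same edgeR test. Column totals as library sizes gave 10165 genes, 9443 higher and 722 lower, a split that followed the shift of the median.

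**Figure D1:**
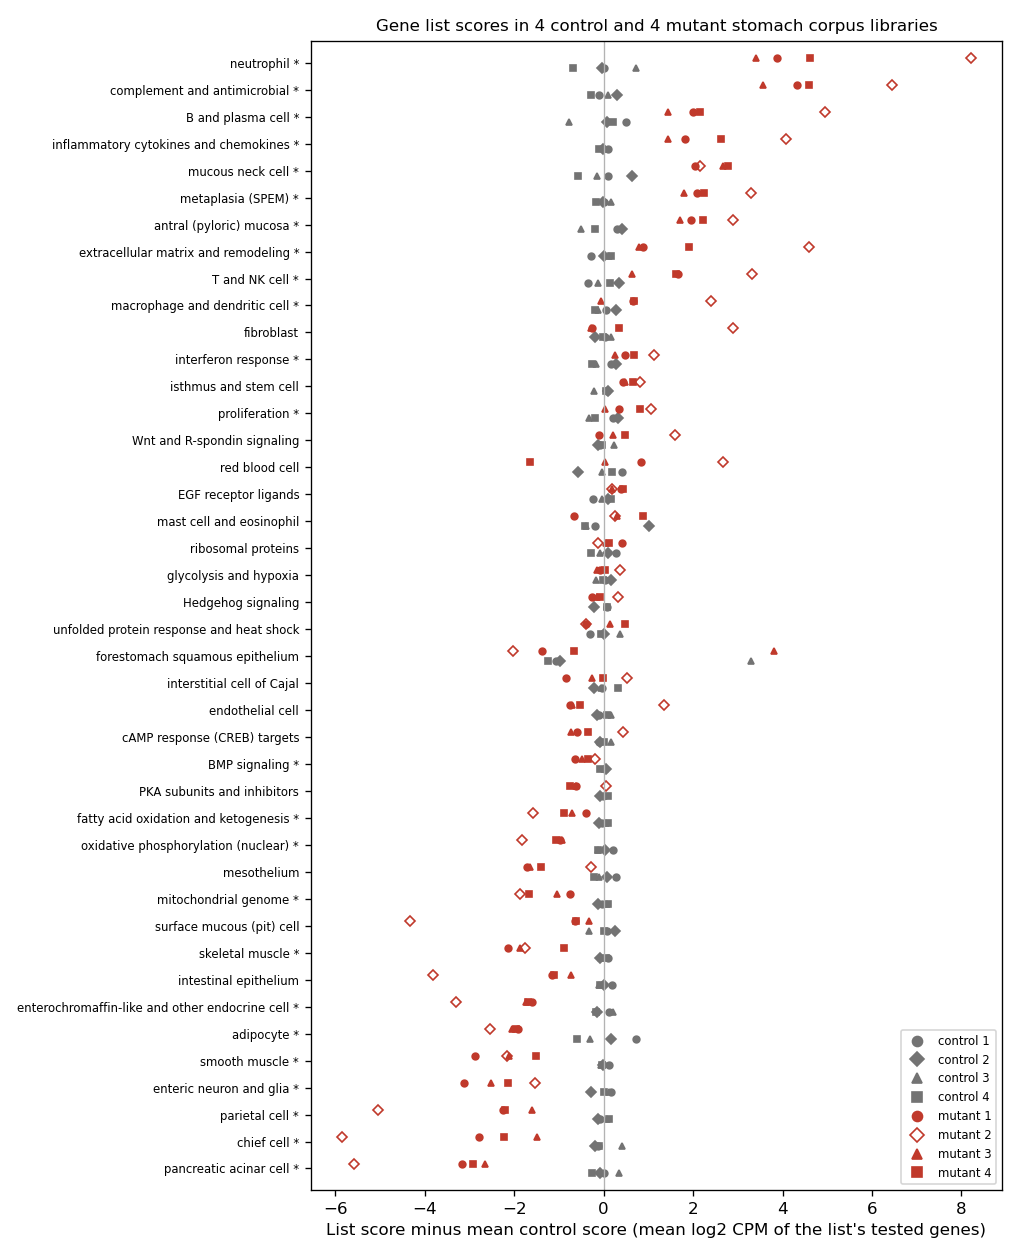
Each row is a gene list fixed before the data were examined, and each point is 1 library's mean log2 CPM over the list's tested genes minus the mean of the 4 controls (grey, controls; red, mutants; the open diamond is mutant 2). Asterisks mark the 24 lists past camera with a preset correlation, of which 12 lie higher and 12 lower in mutants.

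The lists of the acid-secreting parietal cell and of the enzyme-secreting chief cell were lower by camera. In the parietal list, 10 of 18 tested genes were lower, 8 were not called and none was higher (camera adjusted p = 1.29e-09, and adjusted p = 0.255 with an estimated correlation). The count was 13 lower when adjusted over the list alone. Slc4a2, the basolateral anion exchanger of the parietal cell, went from 632 ± 32.0 to 139 ± 33.1 CPM (log2 fold change -2.18, SE 0.20, adjusted p = 0.000929). Hrh2, the histamine receptor that drives acid secretion, changed by -3.17 (SE 0.29), and Clic6, a chloride channel family gene, by -2.81 (SE 0.40). In the chief cell list, 4 of 9 tested genes were lower and 5 were not called (adjusted p = 4.52e-05, and adjusted p = 0.356 with an estimated correlation), with 7 lower when adjusted over the list alone. Pgc went from 309729 ± 96975 to 16557 ± 15252 CPM (log2 fold change -4.23, SE 1.06, adjusted p = 0.0268). That call was lost when any 1 control, mutant 1 or mutant 4 was left out (adjusted p of at most 0.0786). Chia1, an acidic chitinase of the chief cell, changed by -5.65 (SE 1.32, adjusted p = 0.0209), and lost its call without control 1, control 3 or mutant 4 (adjusted p of at most 0.0632). Rab26, a vesicle-trafficking gene, changed by -2.78 (SE 0.38). Both lists reached their lowest score in mutant 2, and without it 15 parietal genes were lower and 1 higher, and 7 chief cell genes were lower. Without any 1 control or mutant 4, 4 to 6 parietal genes were lower. Chief cell genes lower then numbered 1 or 2, as also without mutant 1. Without mutant 3 Pgc changed by -4.99 and Chia1 by -6.87.

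Digestive enzyme genes of the pancreatic acinar list, which had reads in the corpus libraries, fell in 5 of 7 tested members, and 1 rose (adjusted p = 0.000127, and adjusted p = 0.255 with an estimated correlation). Which cells these reads came from was not tested. Cel, carboxyl ester lipase, changed by -3.95 (SE 0.61), Pnlip, pancreatic lipase, by -5.51 (SE 0.96) and Pnliprp1, a related lipase gene, by -4.74 (SE 0.86). Pnlip changed by -7.86 without mutant 4, and Pnliprp1 by -5.41 without mutant 3. Cela1, an elastase gene, rose by 0.76 (SE 0.16). Adjusted over the list alone, 6 fell and 1 rose. The endocrine cell list fell in 11 of 17 tested members and rose in none (adjusted p = 7.50e-09, and adjusted p = 0.220 with an estimated correlation), with 13 lower when adjusted over the list alone, and 8 with column totals. Scg2, a granin of secretory granules, changed by -3.58 (SE 0.37), Slc18a2, the vesicular monoamine transporter of histamine-storing cells, by -2.98 (SE 0.41) and Scg3 by -2.57 (SE 0.37). Endocrine genes lower numbered 6 or 7 without control 1, 3 or 4 or mutant 4, and acinar genes lower 3 without control 1 or 3 or mutant 4.

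The mucous neck cell and metaplasia lists were higher by camera. In the mucous neck cell list 9 of 10 tested genes were higher and none was lower (adjusted p = 7.54e-08, and adjusted p = 0.192 with an estimated correlation), and all 10 were higher when adjusted over the list alone. Aqp5, a water channel, went from 16.4 ± 9.97 to 193 ± 97.7 CPM (log2 fold change 3.56, SE 0.59, adjusted p = 0.00598). Cftr, the chloride channel, rose by 8.20 (SE 1.38) from a control mean of 0.305 CPM, and Gkn3, a gastrokine, by 3.09 (SE 0.52). The list of spasmolytic polypeptide-expressing metaplasia (SPEM), a mucous cell lineage known to arise in injured corpus, had 10 of 16 tested genes higher and 1 lower (adjusted p = 6.68e-09, and adjusted p = 0.164 with an estimated correlation), with 12 higher and 1 lower when adjusted over the list alone. Wfdc2, a secreted protease-inhibitor family gene, went from 5.24 ± 1.12 to 78.1 ± 9.34 CPM (log2 fold change 3.90, SE 0.19, adjusted p = 0.000113). Muc4, a membrane mucin, rose by 5.63 (SE 0.40), and Dmbt1, a mucosal scavenger receptor, by 6.40 (SE 0.72). Nupr1, a stress-response gene, fell by 1.45 (SE 0.22). The antral mucosa list passed (adjusted p = 0.0271, and adjusted p = 0.356 with an estimated correlation), with 2 of 6 tested genes higher. These were the tight junction genes Cldn2, at 0.414 ± 0.251 CPM in controls and 183 ± 222 in mutants, and Cldn7, which rose by 3.28 (SE 0.66), while Lgr5, a stem cell receptor, was not called (0.60, SE 0.25). That list lost its call without control 4 (adjusted p = 0.0678) and with column totals (adjusted p = 0.237). Without mutant 2 Cftr rose by 6.61 (SE 0.92), Cldn2 by 7.51 (SE 0.90) and Cldn7 by 2.21 (SE 0.21), and without control 2 Cftr rose by 8.88. Mucous neck genes higher numbered 5 without control 1 or 4, and 2 metaplasia genes were lower without mutant 2.

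**Figure D2:**
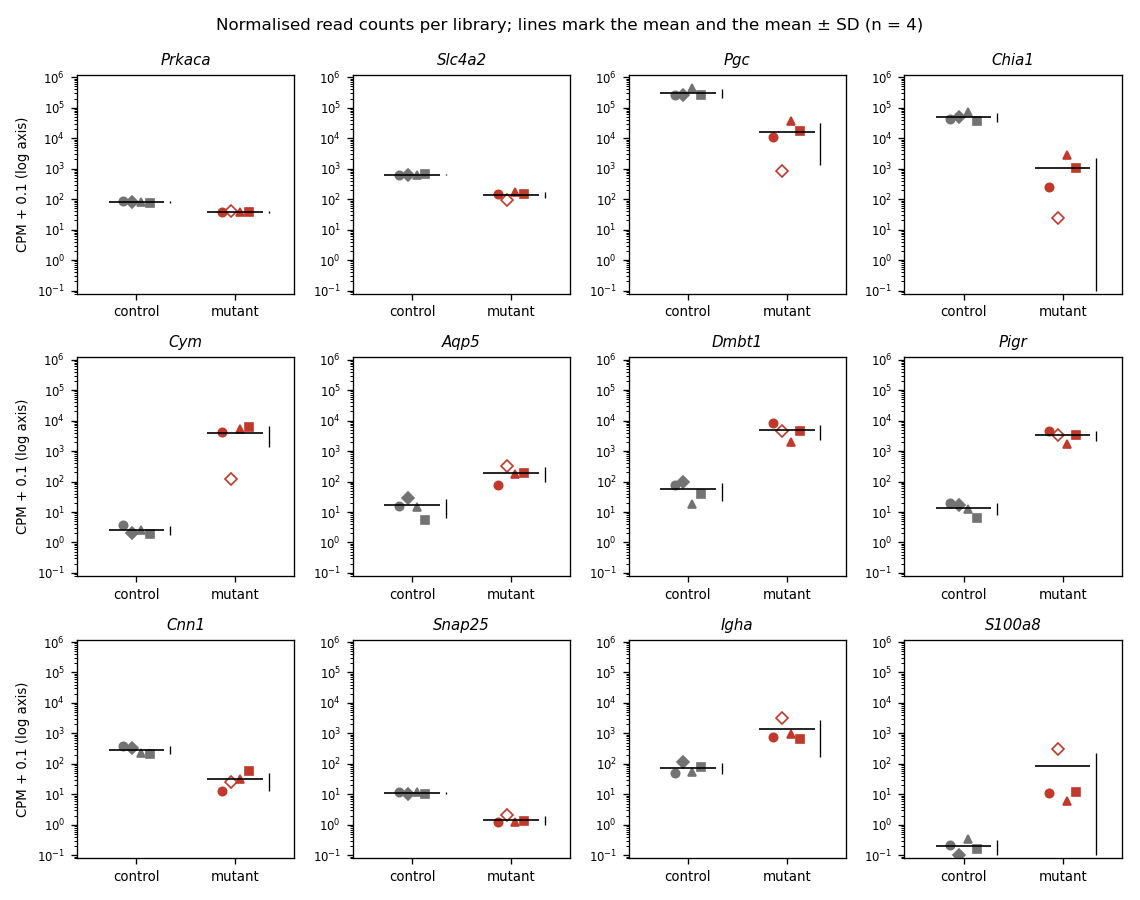
Normalised read counts (CPM plus 0.1, log axis) of 12 genes in 4 control and 4 mutant libraries. Points are libraries (the open diamond is mutant 2), horizontal lines are group means and vertical bars the mean ± SD, ended at the axis floor where the SD exceeds the mean. Prkaca and the epithelial, muscle and neuron genes Slc4a2, Pgc, Chia1, Cnn1 and Snap25 lie lower in every mutant than in every control, and the other 6 genes lie higher.

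Other epithelial lists did not pass camera with the main settings. The pit and intestinal scores still lay below every control in 4 of 4 mutants, and the isthmus score above (exact permutation test, adjusted p = 0.0462 each). In the pit cell list, of the surface mucous lineage, Gcnt1, a mucin-type glycosyltransferase, was the sole gene called of 13 (0.96 higher, SE 0.19, adjusted p = 0.0109), and the list test gave an adjusted p of 0.0601. Mutant 2 held a pit cell score of 5.41, against 9.09 to 9.41 in the other mutants, and without it 8 pit cell genes were lower and 2 higher (list adjusted p = 0.0467, and 0.561 with an estimated correlation). The pit list also passed without control 3 or mutants 1, 3 or 4 (adjusted p = 0.0226, 0.0349, 0.0245 and 0.0259) and with column totals (adjusted p = 0.0010). The isthmus and stem cell list had 3 of 12 genes higher and 1 lower (adjusted p = 0.0539, and 0.0141 by fry). Without mutant 2 it passed, with 4 higher and 3 lower (adjusted p = 0.0178, and 0.162 with an estimated correlation), as it did without mutants 1 or 3 (adjusted p = 0.0355 and 0.0245). With column totals 10 isthmus genes were higher and none was lower (adjusted p = 0.111). Prom1, a progenitor surface marker, rose by 2.10 (SE 0.19), and Bmi1, a polycomb gene, was lower by 0.38 (log2 fold change -0.38, SE 0.11, adjusted p = 0.0462). Bmi1 turned to 0.32 with column totals as library sizes and lost its call without control 2, 3 or 4 or mutant 1, 3 or 4 (adjusted p of at most 0.123). The intestinal list had 2 genes higher and 3 lower of 8 (adjusted p = 0.243, and 0.0092 with column totals, given as down), among them Vil1, the brush-border villin, which rose by 1.90 (SE 0.27). Without any 1 library except mutants 2 and 3, 1 intestinal gene was higher and 1 lower. The counts were 3 and 5 without mutant 2, and 1 and 3 without mutant 3, where 5 isthmus genes were higher. In the forestomach squamous list none of 7 genes was called (adjusted p = 0.886, largest evidence for Ivl, 1.6, SE 1.02). Control 3 and mutant 3 nevertheless held squamous transcripts, with forestomach scores of 5.18 and 5.70 against -0.134 to 1.24 in the other 6 libraries, and 484 and 3776 reads of Krt5, a basal squamous keratin, against at most 1. With both of these libraries left out, a choice made after seeing the data, 1410 genes differed. Adjusted over the list alone, the pit, isthmus, intestinal and forestomach lists had 1, 4, 2 and 0 genes higher and 0, 2, 4 and 0 lower.

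Lists of the muscle wall and its nerves were lower by camera. The smooth muscle list was lower in 11 of 12 tested genes (adjusted p = 6.48e-11, and adjusted p = 0.164 with an estimated correlation), also when adjusted over the list alone. Cnn1, calponin, went from 289 ± 84.3 to 31.9 ± 19.5 CPM (log2 fold change -3.18, SE 0.46, adjusted p = 0.0037), Mylk, myosin light chain kinase, changed by -1.78 (SE 0.24) and Hspb6, a small heat shock protein gene of muscle, by -1.55 (SE 0.21). The enteric neuron and glia list was lower in 7 of 11 genes (adjusted p = 5.65e-09, and adjusted p = 0.192 with an estimated correlation), or in 8 when adjusted over the list alone. Snap25, a synaptic vesicle fusion gene, changed by -3.01 (SE 0.27) and Elavl4, a neuronal RNA-binding protein gene, by -3.30 (SE 0.43). The adipocyte list was lower in 4 of 7 genes (adjusted p = 0.00318, and adjusted p = 0.227 with an estimated correlation), among them Car3, a carbonic anhydrase, by -6.21 (SE 1.06) and Fabp4, a fatty acid binding protein gene, by -1.42 (SE 0.30). With column totals 2 adipocyte genes were lower, and without control 1 Car3 changed by -5.23. The skeletal muscle list passed (adjusted p = 0.0426, and adjusted p = 0.255 with an estimated correlation) with 1 of 4 genes lower, Ckm, muscle creatine kinase (-4.50, SE 0.85), while Mylpf (-0.83, SE 0.28) and Tnni2 (-0.83, SE 0.51) were not called. That list lost its call without control 4 or mutants 1, 2 or 3 (adjusted p of 0.0522, 0.0522, 0.0826 and 0.109), and without mutant 4 Ckm changed by -5.66. It also lost its call with DESeq2, limma-voom, the replicate block and the Y-linked covariate, and without both squamous libraries (adjusted p = 0.0679, 0.0750, 0.0653, 0.0630 and 0.0943). With the smooth muscle score as a covariate no gene was called by edgeR, and 743 had an unadjusted p under 0.05. The groups accounted for 90.7% of the variance of that score, so the fit could hardly separate the genotype from it.

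Fibroblast, endothelial, interstitial cell of Cajal, mesothelium, red blood cell and mast cell and eosinophil lists did not pass (adjusted p = 0.170, 0.663, 0.968, 0.103, 0.433 and 0.611). Their genes with the smallest p were Pdgfra, a platelet-derived growth factor receptor gene (1.86 higher, SE 0.42, adjusted p = 0.0189), Gja1, a gap junction gene (1.24 higher, SE 0.30), Prox1, a lymphatic transcription factor (-0.99, SE 0.28), Gpm6a, a membrane glycoprotein gene (-3.47, SE 0.25), Alas2, an erythroid heme enzyme (1.46, SE 0.77, not called) and Siglecf, an eosinophil receptor (1.68 higher, SE 0.49, adjusted p = 0.0455). In the mesothelium list, which passed fry (adjusted p = 0.0119), Gpm6a fell and Msln, mesothelin, rose by 1.89 (SE 0.28), the latter named after its values were seen. That list also passed camera with column totals, as down (adjusted p = 0.00536), and in further fits given below. Adjusted over the list alone, the fibroblast, Cajal cell and mesothelium lists had 1 gene higher each, the mesothelium list 1 lower, and the other 3 lists none. The calls of Pdgfra, Gja1, Prox1 and Siglecf were lost on leaving out some single libraries: Pdgfra without control 1, 2 or 3, Gja1 without control 1, 2 or 4, and Prox1 and Siglecf without any control, mutant 3 or mutant 4 (adjusted p of at most 0.0651, 0.0799, 0.107 and 0.119). In mutant 2 the fibroblast score was 8.32, against 5.15 to 5.77 in the other mutants, and the endothelial score 6.06, against 3.96 to 4.18. For the endothelial list the mean log2 fold change was 0.22 and the median 0.12, whereas camera gave its direction as down. Without mutant 2, 9 of 12 endothelial genes were lower (adjusted p = 0.000529, and 0.286 with an estimated correlation), and the mesothelium list passed with 3 lower and 1 higher (adjusted p = 0.00848, and 0.162 with an estimated correlation). Pdgfra rose by 1.24 (SE 0.15) and Alas2 stood at 0.25 (SE 0.43, not called) without mutant 2. The fibroblast list passed without mutant 1 or 3 (adjusted p = 0.0414 and 0.0372), and with column totals 11 of its 15 genes and 2 endothelial genes were higher. With an estimated correlation and all libraries the adjusted p of the fibroblast list was 0.832. Leaving out mutant 2 gave 3 fibroblast, 2 Cajal cell and 1 mast cell or eosinophil gene lower, and 2 Cajal cell genes higher. Fibroblast genes higher numbered 2 without mutant 1 or 3, and without mutant 1 there were 1 fibroblast and 2 mesothelium genes lower.

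The antimicrobial and cytokine lists and 4 of the 5 lists of immune cells were higher by camera, with the mast cell and eosinophil list the exception. In the complement and antimicrobial list 13 of 15 genes were higher and none was lower (adjusted p = 7.68e-13, and adjusted p = 0.192 with an estimated correlation), and all 15 were higher when adjusted over the list alone. Pigr, the receptor that carries immunoglobulin A into the lumen, went from 13.6 ± 5.65 to 3291 ± 1184 CPM (log2 fold change 7.92, SE 0.54, adjusted p = 0.000536). The cytokine and chemokine list had 13 of 25 genes higher and none lower (adjusted p = 2.52e-06, and adjusted p = 0.370 with an estimated correlation), or 18 adjusted over the list alone. Ccl20, a chemokine for lymphocytes and dendritic cells, rose by 6.02 (SE 1.02) from a control mean of 0.184 CPM, Il1a by 5.39 (SE 1.01) and Cxcl13, a B cell chemokine, by 2.29 (SE 0.44). The neutrophil list was higher in 5 of 7 genes (adjusted p = 0.00227, and adjusted p = 0.430 with an estimated correlation), S100a8, S100a9 and the chemokine receptor gene Cxcr2 among them (9.47, SE 1.97, then 9.75, SE 1.87, and 7.55, SE 1.73). The count was also 5 when adjusted over the list alone. The B and plasma cell list was higher in 7 of 14 genes, or in 11 adjusted over the list alone (adjusted p = 4.40e-05, and adjusted p = 0.430 with an estimated correlation). Igha, the immunoglobulin A heavy chain, rose by 4.26 (SE 0.63), Jchain, its joining chain, by 3.98 (SE 0.73) and Pou2af1, a B cell coactivator, by 4.03 (SE 0.79). The call of S100a8 was lost without control 1 and that of Cxcr2 without any 1 control (adjusted p of at most 0.0507 and 0.0603). Mutant 2 enlarged several of these rises. Without it S100a8, S100a9 and Cxcr2 rose by 6.36 (SE 0.51), 6.88 (SE 0.46) and 5.23 (SE 0.88), Ccl20 and Il1a by 5.01 (SE 0.58) and 4.38 (SE 0.64), and Igha, Jchain and Pou2af1 by 3.42 (SE 0.29), 3.06 (SE 0.48) and 2.96 (SE 0.40). Without control 1 Cxcr2 stood at 8.92 (not called) and Il1a at 6.34, without control 3 S100a8 at 10.25, and without control 4 Ccl20 at 6.80.

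The T and NK cell list was higher in 5 of 9 genes, or in 6 adjusted over the list alone (adjusted p = 0.00164, and adjusted p = 0.435 with an estimated correlation), with Cd3e at 3.29 (SE 0.70), Cd3g at 3.57 (SE 0.94) and Cd5 at 2.42 (SE 0.58). The macrophage and dendritic cell list was higher in 2 of 15 genes, or in 1 adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.606 with an estimated correlation). These were Itgax, an integrin (1.76, SE 0.38), and Fcgr1, an Fc receptor (2.31, SE 0.67), while Lyz2, a lysozyme gene, was not called (1.69, SE 0.56). The calls of Cd3e (without control 2 or 3), Cd5 (control 1, 2 or 3), Itgax (control 1 or 3), Cd3g (any control or mutant 1) and Fcgr1 (any control or mutant 4) were lost, with an adjusted p of at most 0.0511, 0.0687, 0.0563, 0.096 and 0.118. The interferon list was higher in 7 of 30 genes, or in 10 adjusted over the list alone (adjusted p = 0.000289, and adjusted p = 0.406 with an estimated correlation), with Oasl2 at 1.16 (SE 0.18), Stat2 at 0.50 (SE 0.083) and the class I histocompatibility gene H2-K1 at 0.96 (SE 0.18). The extracellular matrix list was higher in 9 of 28 genes, or in 22 adjusted over the list alone (adjusted p = 8.93e-06, and adjusted p = 0.503 with an estimated correlation). Col18a1, a basement membrane collagen, rose by 2.64 (SE 0.19) and Adamts4, a matrix protease, by 3.77 (SE 0.70). Mutant 2 had the highest score of all 8 libraries in the complement, cytokine, neutrophil, B cell, T cell, macrophage, interferon and matrix lists. Without it these lists had, in this order, 11, 15, 4, 7, 6, 3, 11 and 15 genes higher, and 1 cytokine gene lower. Cd3e, Cd3g, Fcgr1 and Adamts4 then rose by 2.52 (SE 0.51), 2.58 (SE 0.63), 1.18 (SE 0.26) and 2.90 (SE 0.42), and Lyz2 was called at 0.76 (SE 0.18, adjusted p = 0.0102). Leaving out any 1 control lowered the counts of genes higher to 7 to 10, 4 to 7, 1 to 3, 3 to 5, 0 to 2, 0 to 1, 4 to 5 and 2 to 3, in the same order of lists. No T cell gene was called without control 2 or 3, and no macrophage gene without control 1 or 3. Leaving out mutant 4 gave 8 cytokine, 1 macrophage and 4 interferon genes, mutant 1 gave 3 T cell and 14 matrix genes, and mutant 3 gave 4 macrophage and 14 matrix genes. With column totals as library sizes the T cell, B cell, macrophage, neutrophil, cytokine and matrix lists no longer stood apart from other genes (adjusted p = 0.206, 0.144, 0.292, 0.353, 0.0684 and 0.163), although 8, 12, 15, 6, 21 and 25 of their genes were higher, as were 23 interferon genes. The T cell, B cell, macrophage, neutrophil and matrix lists did not pass fry either (adjusted p = 0.0759, 0.0732, 0.237, 0.0759 and 0.155).

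Among signalling lists, genes of the bone morphogenetic protein (BMP) list were lower in 6 and higher in 1 of 16 tested members (adjusted p = 0.00164, and adjusted p = 0.164 with an estimated correlation), or lower in 8 and higher in 2 adjusted over the list alone. The BMP target genes Id2 and Smad7 changed by -1.27 (SE 0.11) and -0.84 (SE 0.089), and Grem1, a BMP antagonist gene, rose by 4.04 (SE 0.89). With column totals Smad7 was not called (-0.15, adjusted p = 0.308), and the mean of the list turned from -0.12 to 0.59, with the test still giving down. Grem1 was at 17.3 ± 3.42 CPM in controls and 285 ± 376 in mutants, and lost its call without any 1 control (adjusted p of at most 0.0587). Mutant 2 held 845 CPM of it, and without that library Grem1 rose by 2.5 (SE 0.33). The Wnt list had 4 genes higher and 1 lower of 19 (adjusted p = 0.0730, and 0.475 with an estimated correlation), the lower being Nkd1, a Wnt feedback inhibitor (-1.38, SE 0.24). It passed without mutant 1 at the preset correlation (adjusted p = 0.0310). The EGF receptor ligand list had 4 higher and 2 lower of 12 (adjusted p = 0.240), with Egf at 23.2 ± 7.76 CPM in controls and 1.42 ± 0.496 in mutants (log2 fold change -4.02, SE 0.34, adjusted p = 0.000785). The Hedgehog list had no gene called of 14 (adjusted p = 0.410, Smo at 0.56, SE 0.20), whereas 2 were higher and 3 lower without mutant 2. The cyclic AMP response list had 2 genes lower of 19 (adjusted p = 0.257), among them Ppargc1a, a coactivator of mitochondrial biogenesis (log2 fold change -0.996, SE 0.17, and -0.31 with column totals, where it was not called). Without mutant 2, 6 of its genes were lower and the list passed (adjusted p = 0.0329, and 0.265 with an estimated correlation). With column totals the BMP, Wnt, EGF, Hedgehog and cyclic AMP lists had 4, 13, 8, 6 and 6 genes higher and 2, 1, 1, 0 and 1 lower. Without any 1 control, or mutant 4, Wnt genes higher numbered 1 or 2, and without mutant 2 there were 9 BMP genes lower and 2 higher, and 2 Wnt genes lower. No BMP gene was higher without any 1 control, 2 were without mutant 3, and EGF genes higher numbered 2 without control 1 or 3 or mutant 4, and 1 was lower without control 3 or mutant 4. Adjusted over the list alone, the Wnt, EGF and cyclic AMP lists had 4, 6 and 0 genes higher and 1, 2 and 2 lower, and the PKA list 2 lower. The proliferation list was higher in 7 of 26 genes (adjusted p = 0.000295, and adjusted p = 0.494 with an estimated correlation), also adjusted over the list alone, with the replication helicase genes Mcm4 at 0.99 (SE 0.14) and Mcm2 at 0.63 (SE 0.13) and the mitotic kinase gene Plk1 at 0.92 (SE 0.20). Its fry test gave an adjusted p of 0.0804, and with column totals 21 of its genes were higher. That number was 3 without control 3, and 4 without control 4 or mutant 4.

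Lists of mitochondrial energy metabolism were lower by camera. Of 28 nuclear genes of oxidative phosphorylation, 27 were lower and none was higher (adjusted p = 1.98e-19, and adjusted p = 0.255 with an estimated correlation), also adjusted over the list alone, with a mean log2 fold change of -1.17, or -0.48 with column totals, where 8 were lower. Ndufs1 and Ndufa1 of complex I changed by -1.15 (SE 0.14) and -1.30 (SE 0.16), and Uqcrfs1 of complex III by -1.57 (SE 0.20). In the mitochondrial genome list 10 of 13 genes were lower, or 12 adjusted over the list alone (adjusted p = 7.42e-09, and adjusted p = 0.257 with an estimated correlation), mt-Co3 by -1.20 (SE 0.16), mt-Nd6 by -1.63 (SE 0.26) and mt-Nd1 by -1.37 (SE 0.26). The fatty acid oxidation list was lower in 6 of 17 genes, or in 12 adjusted over the list alone (adjusted p = 1.35e-06, and adjusted p = 0.356 with an estimated correlation). Acadm, medium-chain acyl-CoA dehydrogenase, changed by -1.44 (SE 0.15), Etfa, an electron transfer flavoprotein gene, by -1.53 (SE 0.24) and Acadl by -0.66 (SE 0.10), the last turning to 0.041 with column totals. With that scaling 7 genes of the mitochondrial genome and 2 of fatty acid oxidation were lower, and these lists still passed camera (adjusted p = 3.64e-09 and 9.98e-06). Fatty acid oxidation genes lower numbered 11 without mutant 2, and those of the mitochondrial genome 6 without control 1. The parietal cell scores of the same libraries were 7.13 to 7.38 in controls and 2.21 to 5.65 in mutants. The glycolysis list had 1 gene higher and 3 lower of 18 (adjusted p = 0.639, mean 0.10, median -0.097), Hk2, a hexokinase gene, being the one that rose (2.61, SE 0.34). Without mutant 2, 5 glycolysis genes were lower, and without any other 1 library 1 was, while 2 were higher without mutant 1. The unfolded protein response list had 1 higher and 1 lower of 20 (adjusted p = 0.906), Pdia4, a disulfide isomerase gene, by 1.02 (SE 0.16) and Herpud1 by -1.24 (SE 0.36, adjusted p = 0.0455), whose call was lost without control 2, 3 or 4 or mutant 1, 3 or 4 (adjusted p of at most 0.11). Without mutant 2, 4 genes of that list were higher and 3 lower, and without control 1, 2 were lower. Adjusted over the list alone, the glycolysis list had 1 higher and 3 lower, the unfolded protein response list 1 higher, and the ribosomal list none. In the ribosomal protein list none of 26 genes was called by edgeR (adjusted p = 0.348 for the list, and 0.900 with an estimated correlation, Rps19 at 0.27, SE 0.18). With column totals all 26 were higher, with 9 glycolysis and 12 unfolded protein response genes, and without control 1 the ribosomal list passed (adjusted p = 0.0474).

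The largest rises named come from called genes whose groups did not overlap. Cym, the milk-clotting protease chymosin (ENSMUSG00000046213, chromosome 3, 107211293 to 107221732), went from 2.48 ± 0.831 to 3982 ± 2668 CPM (log2 fold change 10.65, SE 1.30, adjusted p = 0.00206). Cxcl5, a neutrophil chemokine gene, had no read in any control and 60.1 ± 94.1 CPM in mutants. Against a floor of 3 counts per control library it was at least 318-fold higher (adjusted p = 0.0317), and its call was lost without any 1 control, mutant 1 or mutant 4 (adjusted p of at most 0.0686). Mutant 2 held 200.8 CPM of Cxcl5, and without it the bound was 69.7-fold. Reg3b, Mmp7, Wfdc18, Mmp10 and Clec4e had 1 read over the 4 controls, and their mutant to control count ratios were 8955 (95% exact counting interval 1607 to 353700), 1897 (340.2 to 74940), 1703 (305.4 to 67280), 1260 (225.9 to 49790) and 1113 (199.5 to 43980). Most of the mutant reads of Mmp7, Wfdc18, Mmp10 and Clec4e lay in mutant 2. Without it the ratios of the 5 genes were 4943 (886.9 to 195300), 98.8 (17.39 to 3935), 292.3 (52.11 to 11580), 289.8 (51.67 to 11480) and 204.2 (36.32 to 8100). The call of Mmp7 was lost without any 1 control, that of Wfdc18 without control 2, and those of Mmp10 and Clec4e without control 4 (adjusted p of at most 0.133, 0.079, 0.078 and 0.0765). Reg3b and Reg3g encode antimicrobial lectins that can share reads, and Reg3g rose by 9.58 (SE 1.78), by 7.48 (SE 1.10) without mutant 2 and by 11.61 without control 2. The largest falls named, under the same rule, included Cfd, the adipocyte complement factor D gene, and Slc10a4, a transporter gene of neurons, with no read in any mutant and at least 90.6-fold and 17.0-fold lower against 3 counts per mutant library. Without control 1, which held 27.44 CPM of Cfd, its bound was 44.7-fold. Try10, a trypsin gene whose family members can share reads, changed by -7.93 (SE 0.83), Slc27a2, a fatty acid transporter gene, by -6.08 (SE 0.69), Tacr2, a tachykinin receptor gene of smooth muscle, by -5.96 (SE 0.80), Sostdc1, a BMP and Wnt antagonist gene, by -5.88 (SE 0.43), Scn4b, a sodium channel subunit gene, by -5.74 (SE 0.61) and Kap by -5.56 (SE 0.90). Tacr2 changed by -7.33 without mutant 4, and Kap by -6.58 (SE 0.94) without mutant 2.

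Other fits ended further calls. Without the low-count filter these were Cxcl5, Mmp7, Bmi1, Prox1, Fcgr1 and Herpud1 (adjusted p of at most 0.131), and with the replicate block Pgc, Bmi1, Prox1, Cd3e, Cd3g, Fcgr1, Siglecf, Grem1, Mcm2, Plk1, Cxcl13 and Herpud1 (at most 0.095). The Y-linked covariate ended those of Bmi1, Pdgfra, Gja1, Prox1, Cd5, Cd3g, Fcgr1, Siglecf and Herpud1 (at most 0.135), and limma-voom that of Siglecf (0.0553). Column totals ended those of Prox1 (-0.29), Fabp4 (-0.71) and Herpud1 (-0.51) besides those given above, and made Lgr5 (1.30), Alas2 (2.17), Lyz2 (2.41), Smo (1.27) and Rps19 (0.97) called. The FPKM fits with a filter ended 10 (pseudocount 1) and 4 (pseudocount 0.1) calls of named genes, the FPKM fit without one ended 22, and leaving out both squamous libraries ended 20. Lyz2 was also called by DESeq2 and limma-voom, Mylpf by DESeq2, and Six2 and Smo by limma-voom. Among lists, limma-voom ended the call of the antral list (adjusted p = 0.0568) and the stricter filter that of the T cell list (adjusted p = 0.0693). The PKA list passed with DESeq2 and limma-voom (adjusted p = 0.0452 and 0.0050), the cyclic AMP and endothelial lists with limma-voom (adjusted p = 0.0371 and 0.0023), and the fibroblast and Wnt lists with DESeq2 (adjusted p = 0.0452 for both). Without the low-count filter the pit, isthmus, mesothelium, PKA and Wnt lists passed (adjusted p = 0.0104, 0.0090, 0.0190, 0.0190 and 0.0416). The isthmus and mesothelium lists passed with the replicate block (0.0362 and 0.0339) and the Y-linked covariate (0.0424 and 0.0372). Mesothelium also passed with limma-voom (0.0465), and PKA with the stricter filter (0.0449) and the Y-linked covariate (0.0488).

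The sex-linked genes, fixed as a check, did not follow the groups. Xist held 5435, 5892 and 6994 reads in controls 1, 3 and 4 and 10278 and 10874 in mutants 3 and 4, and at most 2 in control 2 and mutants 1 and 2. Those 3 libraries held 616, 1368 and 1629 reads of the Y-linked gene Ddx3y, where the other 5 held at most 1. Xist was not called between groups (log2 fold change -0.32, SE 2.16, adjusted p = 0.927). With the libraries' Y-linked score as a covariate 2069 genes differed, 840 higher and 1229 lower.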

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

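Of the tests in this part, the count over other splits of the libraries was chosen before its result was seen, the fits without mutant 2 and with scaling on genes outside the parietal and chief lists were planned but used as tests of explanations only after, and the other tests were chosen after. In groups of 4 libraries, a library was singled out where its gap to the nearest other, divided by the group's range, exceeded Dixon's limit of 0.83. This held in 34 of 304 groups, where chance gives 15.2, and 12 of the 34 lay in mutant 2.

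Mutant 2 was the low library among mutants for the pit cell (gap over range 0.921), endocrine (0.931), intestinal (0.866), pancreatic acinar (0.83) and oxidative phosphorylation (0.862) scores and for Cym (0.917) and Uqcrfs1 (0.919). It was the high one for the endothelial score (0.893), Prkaca (0.928), Mmp7 (0.864), S100a8 (0.84) and Snap25 (0.865). Against the mean of the other mutants its scores lay at -3.80 for pit, -3.67 for chief, -3.03 for parietal, -0.34 for mucous neck and 1.25 for metaplasia genes, and at 2.95 for fibroblast and 4.24 for neutrophil genes (log2). Low depth is argued against, since its total was 1.03 times the smallest of the other libraries. For a control animal under a mutant label, the Prkaca level alone cannot decide, since it depended on the scaling. That level was 0.508 of the control mean by TMM and 0.8462 with column totals, where control 3 held 0.8479. The whole profile argues against an animal like the 4 controls. Its log2 CPM correlated with theirs at 0.749 to 0.761, against 0.885 to 0.924 for the other mutants. Its parietal score was 2.21 (controls 7.13 to 7.38) and its metaplasia score 7.21 (controls 3.75 to 4.09). A lower share of mucosa of unchanged makeup would lower epithelial lists alike, but their shifts spanned 5.05. Within any single one of these lists the scores of the other mutants spanned at most 1.30. A different extent of the same change in that animal was not tested. It may remain for lists that went further the same way, such as those of parietal, chief and metaplasia genes. The endothelial score of mutant 2 was 6.06, above the controls (4.56 to 4.89), while the other mutants lay below them (3.96 to 4.18). For that list a greater extent alone is argued against.

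The smooth muscle and enteric neuron list scores lay below every control in every mutant. The scaling is argued against as the whole cause, since with column totals the lists' mean log2 fold changes stayed at -1.36 and -1.66. An equal dilution of all stromal cells by more mucosa is argued against too, since without mutant 2 the fibroblast median lay 2.30 above that of smooth muscle (median absolute deviation 0.79). The medians of the endothelial, Cajal cell, mesothelium and enteric neuron lists were then -0.64, -0.68, -1.22 and -3.21, all lower than in controls. These values cannot decide on a dilution that spares fibroblast genes. Less outer wall in the dissected pieces stays open. The mesothelium score lay below every control in 4 of 4 mutants. That of interstitial cells of Cajal, which lie in the same wall, did so in 2 of 4. Members of both lists went both ways, in the mesothelium list with Gpm6a lower and Msln higher. A change of the wall with genotype stays open too, and the design cannot separate it from dissection.

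Prkaca was lower in every mutant. Scaling is argued against as the whole cause of the difference between groups, since the call held with column totals (-0.38, SE 0.12, adjusted p = 0.0208), but the size stays open (-1.08 with scaling on genes outside the parietal and chief lists), as does the place of mutant 2: 4 of 4 mutants lay below every control, but mutant 2 at 0.998 of control 3 (95% exact counting interval 0.917 to 1.09). Fewer parietal and chief cells stay open: with the parietal or the chief share as a covariate the log2 fold change was -1.51 (SE 0.38) or -1.25 (SE 0.25), against -1.08 (SE 0.085) without. Both calls ended, since the unadjusted p of 0.00391 and 0.00129, against 8.93e-07 without, did not survive adjustment (0.205 and 0.806) in fits where edgeR called 0 genes (2813 and 792 at an unadjusted p under 0.05, no other tool run) and 95.2% and 87.4% of the shares' variance lay between groups. Little transcript from the modified copy stays open too, since 4 of 4 mutants lay between 0.4 and 0.6 of the control mean by TMM and 0 of 4 with column totals.

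Chance assignment of the libraries is argued against for the number of changed genes: 1 of 35 splits, the real one, gave as many as 3208. That is the smallest share these splits allow. Each other split mixed controls and mutants, so the group difference added to its spread within groups. The highest of the others gave 0 by edgeR, with at most 1739 genes at an unadjusted p under 0.05, against 5765 in the real split. Other tools were not run on these splits.

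Control 3 was high among controls for the share of Pgc (0.895), the top 10 genes' share (0.952), the chief cell (0.873) and forestomach (0.943) scores and Pgc (0.935), and low for the isthmus score (0.862). Control 2 was high for the mast cell score (0.846), Reg3g (0.84), Id2 (0.858) and Oasl2 (0.844), and low for the Hedgehog score (0.942) and Mylk (0.911). Control 4 was low for Slc10a4 (0.982) and mt-Nd6 (0.941), and control 1 for Cldn7 (0.938). Mutant 1 had a high total (0.909), and mutant 4 was low for mt-Co3 (0.867). Reg3b, Mmp7 and Wfdc18 had their 1 control read in control 2, and Mmp10 and Clec4e in control 4, which makes the gap over range 1.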

How the results depend on the processing

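Column totals as library sizes and the fit without both squamous libraries were chosen after the result was seen. Of 97 named genes called, 76 stayed past the threshold in each fit without 1 library and 62 in each other gene fit except the smooth muscle covariate, 60 in both. In those other fits a gene without an adjusted p counted as staying. DESeq2, the stricter filter and the FPKM fits with a filter left some named genes without one. Most named genes were taken for a small p or a large change in these data, so their staying does not stand for all calls. Of all 3208 calls, 1664 stayed without control 1, 1846 without control 2, 1681 without control 3 and 3185 without mutant 2. Of 24 called lists, 22 stayed in each fit without 1 library, and 11 in all settings but the estimated correlation, where 0 passed.

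Against 3208 changed genes, 1489 higher and 1719 lower, fits without 1 library gave 1717 (without control 1) to 5400 (without mutant 2) changed, 665 to 2447 higher and 1018 to 2953 lower, with 22 to 29 lists. Fewer animals were tested in each. DESeq2 called 2309 higher, limma-voom 5668 changed (2602 higher, 3066 lower, mutant 2 weighted 0.102), and FPKM without a filter 827 higher. Stricter thresholds left, by construction, 1910 (863 and 1047) at 2-fold or more, and 1047 (380 and 667) at 0.01. Column totals gave 10165 (9443 and 722), or 92.9% higher against 46.4%, as the median shifted by 0.70. Such totals include the 10 most abundant genes, which took 38.8% to 50.8% of reads in controls and 8.69% to 15% in mutants. That drop raises the summed share of all other genes in mutants. With RLE factors, or scaling outside the parietal and chief lists, the median stayed at 0.065 and 0.066, against 0.067. Bmi1 (0.32) and Acadl (0.041) reversed with column totals. Without both squamous libraries 1410 genes were called (587 and 823). The Y-linked covariate gave 2069 (840 higher), and Xist reversed to 0.88. Apart from these constructions the cause was not tested.

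With the smooth muscle covariate edgeR called 0 genes, 0 higher and 0 lower (743 at an unadjusted p under 0.05, no other tool run), and 90.7% of the score's variance lies between groups. Reversed there were Cfd (5.82), Tacr2 (1.00), Pnlip (3.06), Cnn1 (0.20), Ckm (2.86) and the smooth muscle (0.034) and skeletal muscle (1.07) lists.

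With the replicate block 1824 genes were called (747 and 1077). Same-numbered deviations correlated at 0.046, -0.062, 0.069 and 0.00065, and 1 control matched its own number best. These values gave little sign of pairing across genes. They cannot exclude it, since the deviations of mutant 2 correlated with those of the other mutants at -0.59 to -0.81. Both libraries with squamous transcripts bore the same number, control 3 with 484 Krt5 reads and mutant 3 with 3776. Each also had the highest Pgc share of its group, 31.2% and 4.60%. Pairing of single numbers was not tested.

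Depth limits genes with no reads in a group, which have only bounds against 3 counts per library. In simulated counts edgeR recovered 18% of 2-fold changes, so a gene not called can still differ. That share was not split by depth.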

Other observations

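The genes in this part were chosen after their values were seen, and no explanation was tested for them. Of 15 genes of the circadian clock and its output, 9 were lower, 1 was higher and 5 were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05 over all genes). Dbp, a clock output transcription factor gene, went from 108 ± 22.7 to 13.4 ± 4.94 CPM (SD, n = 4 each, log2 fold change -3.01, SE 0.29, adjusted p = 0.0011). Nr1d1, a clock repressor gene, changed by -1.71 (SE 0.30), Ciart by -1.99 (SE 0.35), Bhlhe41 by -1.85 (SE 0.36), Hlf by -1.64 (SE 0.38), Tef by -1.27 (SE 0.15), Nr1d2 by -0.96 (SE 0.14), Per3 by -0.84 (SE 0.15) and Cry2 by -0.73 (SE 0.14). Arntl, the clock activator gene, rose by 1.23 (SE 0.21). Per1 (-0.80, SE 0.34), Per2 (-0.17, SE 0.28), Cry1 (0.21, SE 0.25), Clock (0.31, SE 0.14) and Npas2 (0.70, SE 0.22) were not called. The counts were the same without mutant 2, and with column totals as library sizes 5 were lower and 4 higher. No test of the 15 as a set was run. The hours at which tissues were collected are not given in the sources used here.

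A further 6 genes outside the fixed lists, picked for their large rises, were higher in every mutant than in every control, and stand for no class of genes. Muc5b, a gel-forming mucin gene of airway and salivary glands, went from 1.39 ± 0.481 to 470 ± 657 CPM (log2 fold change 8.39, SE 1.24, adjusted p = 0.00392). Muc13 rose by 6.97 (SE 0.81), Reg1 by 6.80 (SE 0.70), Chil1 by 8.22 (SE 1.24), Sftpd, a surfactant lectin gene, by 8.05 (SE 0.62) and Lrg1 by 5.92 (SE 0.71). Mutant 2 held 1448 CPM of Muc5b, against 64.3 to 252 in the other mutants. Without it Muc5b rose by 6.69 (SE 0.60), Reg1 by 6.05 (SE 0.34), Chil1 by 7.12 (SE 1.12) and Lrg1 by 5.21 (SE 0.55).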
